A study of Homo sapiens with 16 samples.

How the data were processed

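RNA sequencing of 16 libraries from MDA-MB-231 cells, a human triple-negative breast cancer line, was analysed. The labels describe cells that carry a short hairpin RNA under doxycycline control, either a scrambled control hairpin (shScramble) or a hairpin against AKAP2 (shAKAP2), grown without or with doxycycline, which gives 4 groups of 4 libraries. The labels call the 4 libraries of a group biological replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these libraries. Neither the doxycycline dose, the time of treatment nor the hairpin sequence is given in the sources used here.

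Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads and made into libraries with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, STAR 2.5.2b, featureCounts, Subread 1.5.2 and the genome build GRCh38 were used; the annotation release and whether counting used strand are not given in the sources used here. The authors deposited a table of raw counts, in whole numbers of reads per gene, for 57500 genes with their Ensembl identifiers and symbols, and every count column was matched to a library by its name in the labels. Of the genes, 26937 had no count in any library. For positions and 3' untranslated regions (3' UTRs), identifiers were matched to GENCODE release 29 of GRCh38, in which 56898 of them were found, 56112 with the same symbol. Because no use of strand is stated, genes that overlap on opposite strands cannot be told apart, and counts of paralogs and of overlapping genes are uncertain.

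Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes with enough counts in the 4 groups were kept by filterByExpr, which left 15566, and libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with robust shrinkage and a mean per group was fitted to all 16 libraries, so that the groups share the estimate of the spread, with 12 residual degrees of freedom and a biological coefficient of variation of 14.4%. There were 5 contrasts: doxycycline against none in the shAKAP2 line, the same in the shScramble line, the difference between those effects (the interaction term), and shAKAP2 against shScramble with and without doxycycline. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p of a gene is from edgeR's quasi-likelihood test with that adjustment. Each log2 fold change is given with a standard error (SE) derived from the F statistic, and levels are CPM, counts scaled to TMM-adjusted library size, as mean ± SD over 4 libraries.

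The tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except those named otherwise. The rule named AKAP2 first and then the called genes with the largest fold changes. These had a mean of at least 1 CPM over all 16 libraries. They also had no overlap between the libraries of the groups compared and a symbol that is not a clone name. The rule took 10 in each direction for the shAKAP2 doxycycline effect and for the interaction (with overlap judged in the shAKAP2 line). For the other comparisons it took 5 in each direction. For groups of 4, chance alone separates 2.86% of genes without overlap. From a list, up to 4 members with the smallest p were named, except that some are not reported here, and any other gene is said to have been chosen after its values were seen.

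There were 33 gene lists, written from general knowledge: integrins, focal adhesion, actin and myosin, extracellular matrix, matrix proteases and inhibitors, YAP/TAZ targets, SRF/MRTF targets, mesenchymal genes, epithelial genes, metastasis genes of MDA-MB-231, TGF-beta response, MAPK output, protein kinase A and A-kinase anchors, cAMP/CREB targets, G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis, interferon response, NF-kB response, mitochondrially encoded transcripts, nuclear-encoded oxidative phosphorylation, integrated stress response, unfolded protein response, glycolysis, hypoxia, cholesterol synthesis, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, luminal breast epithelial markers, blood cell markers, fibroblast markers and replication-dependent histones. Some genes stand in more than 1 list. Each list was tested with camera, which compares its genes with all others, at a preset correlation between genes of 0.01 and a Benjamini-Hochberg adjustment over the lists. The same test with the correlation estimated for each list is given beside it, because co-regulated genes can make the preset value too lenient.

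The pipeline was tested on simulated counts drawn from the means and library sizes of the 15566 genes. For the shAKAP2 doxycycline effect it recovered 67.2% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold, with 4.05% false calls. For the interaction the shares were 40.3%, 71.6% and 95.5%, with 6.76% false calls. In the shScramble line 61.2%, 85.1% and 98.5% were recovered, with 5.78% false calls. All simulated groups had the same spread per gene and no library apart from its group, unlike shScramble replicate 1 in the data. The shares may thus not hold for comparisons that use shScramble libraries. In all 5 comparisons camera called 20 of 20 shifted lists, which held many genes changed at least 1.5-fold. Simulated genes were drawn independently of each other, so this says nothing about lists of correlated genes or smaller shifts. Changes were planted only in genes with a mean of at least 1 CPM, so the recovery shares do not cover genes below it.

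Alternatives covered the test (DESeq2 1.42.0 and limma-voom), the scaling, the low-count filter, the libraries in the fit, the threshold, the set test and each library left out in turn. Other assignments of the libraries to groups were refitted, all 35 for comparisons of 4 against 4 and 100 drawn at random for the interaction. Words of 7 letters in the longest annotated 3' UTR were scored for the log2 fold changes of 12807 tested genes that have one, a scan chosen after the data were seen; a planted word ranked 1 in simulated fold changes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the words and figures.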

Results

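Polyadenylated RNA was measured in MDA-MB-231 cells with an inducible shScramble or shAKAP2 hairpin, each without and with doxycycline, the drug that switches the hairpin on. AKAP2 is an A-kinase anchoring protein, a scaffold that binds protein kinase A, and the series is about its role at focal adhesions, the sites where cells attach to matrix. Total counts per library ranged from 24482997 to 37472525, and 15566 genes were tested. The share of counts from mitochondrially encoded genes was 2.2% to 3.62% in shScramble libraries, 1.86% to 2.38% in shAKAP2 libraries without doxycycline and 1.02% to 2.04% in shAKAP2 libraries with it.

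The targeted gene, AKAP2 (ENSG00000241978; GRCh38 chromosome 9, 110048598 to 110172512, plus strand), fell to a few counts when the shAKAP2 hairpin was induced. Its level was 1.42 ± 0.0272 CPM without and 0.0403 ± 0.0583 CPM with doxycycline (SD, n = 4 each), from 168 and 4 counts summed over the libraries. That left 2.67% of the uninduced level (95% interval for counting error 0.72% to 6.97%). Replicate 1 held 3 of the 4 remaining counts, replicate 3 held 1, and replicates 2 and 4 had 0. The log2 fold change was -5.06 (SE 0.577, adjusted p = 1.25e-06), and -6.42 without replicate 1 with doxycycline. In shScramble cells AKAP2 stood at 1.17 ± 0.24 CPM without and 1.76 ± 0.685 CPM with doxycycline, a log2 difference of 0.58 (SE 0.371) that did not pass the test (adjusted p = 0.706). The difference between the lines' doxycycline effects was -5.65 (SE 0.703, adjusted p = 8.48e-06).

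AKAP2 shares 85.8% of its exonic bases with the readthrough gene PALM2-AKAP2 (ENSG00000157654). How reads on shared bases were counted is not known here. If they were left out, the counts of both genes come from their unshared bases only. Neither the CPM of AKAP2 nor the sum of both genes would then give the level of the whole locus. PALM2-AKAP2 fell from 39 to 5 counts in the shAKAP2 line (log2 fold change -2.71, SE 0.851, adjusted p = 0.0213). Summed, both genes fell from 207 to 9 counts, or to 4.88% of the uninduced level. PALM2 (ENSG00000243444), the neighbouring gene, had 122 and 73 counts and was not called (adjusted p = 0.351).

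**Figure D1:**
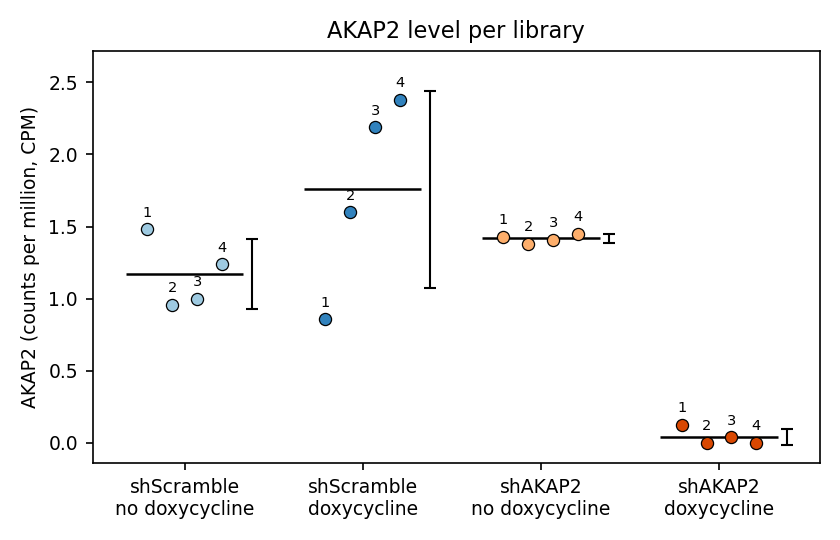
AKAP2 level in CPM (vertical axis) in each of the 16 libraries by group (horizontal axis); points are libraries numbered by replicate, the horizontal line is the mean and the bar is 1 SD either side of it. The 4 shAKAP2 libraries with doxycycline lie at 0.124 CPM or lower, below every other library.

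Doxycycline in the shAKAP2 line was compared first, to find what changed when the AKAP2 hairpin was induced. Among secreted and signalling genes, TNFRSF11B, which encodes the decoy receptor osteoprotegerin, rose 5.33-fold (log2 2.41, SE 0.207) and KISS1, a metastasis suppressor, rose 5.01-fold (log2 2.32, SE 0.213), each with n = 4 against 4. The collagenase gene MMP1 fell (log2 -3.90, SE 0.389), as did MMP3, which encodes stromelysin (log2 -2.62, SE 0.462). HLA-DRA, an MHC class II chain, fell from 15.3 ± 2.16 to 0.959 ± 0.517 CPM (log2 -3.98, SE 0.793). PUDP, a pseudouridine phosphatase, had the smallest p of all genes (log2 fold change -2.67, SE 0.0773, adjusted p = 4.01e-15).

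TMEM236 rose 5.67-fold, and the other genes named by the rule rose by log2 2.56 for TRBC2, 2.33 for KRTAP2-3, 2.12 for PANX2, a pannexin channel, 2.04 for SERPINB7, 2.03 for MARCH4, 1.98 for PDE1C, a phosphodiesterase, and 1.92 for SEMA3E. TRBC2 rose from 0.119 to 0.749 CPM and PDE1C from 0.287 to 1.15 CPM. Both met the floor of 1 CPM only through uninduced and induced shScramble, at 1.44 and 2.16 CPM for TRBC2 and 14 and 13.3 CPM for PDE1C. KRTAP2-3 (adjusted p = 0.0492) and SEMA3E (adjusted p = 0.0358) lost the call when single libraries were left out, 7 of the 8 in each case. Beside AKAP2, the log2 fold change was -4.25 for SLITRK5, -2.84 for ADAMTS14, -2.76 for MAP2K6, a kinase upstream of p38, -2.67 for MAOB and -2.63 for ZNF37BP. HLA-DRA lost its call under limma-voom. Counts of TRBC2, KRTAP2-3 and HLA-DRA, which have close paralogs, and of the pseudogene ZNF37BP are uncertain, and MMP1 and MMP3 overlap WTAPP1.

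In total 2032 genes were higher and 2373 lower, 28.3% of those tested, and 202 and 485 of them changed at least 2-fold, so that 70.6% of the 2-fold changes were falls. Among genes with an annotated 3' UTR, the 7-letter word GAACACA stood in it for 30.8% of 2166 lower genes, 5.5% of 1911 higher genes and 9.8% of 8730 genes not called. AKAP2, SLITRK5, HLA-DRA, MMP1, ADAMTS14, MAOB and PUDP each hold 1 copy, while MMP3, MAP2K6 and the named genes that rose and have an annotated 3' UTR hold none.

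**Figure D2:**
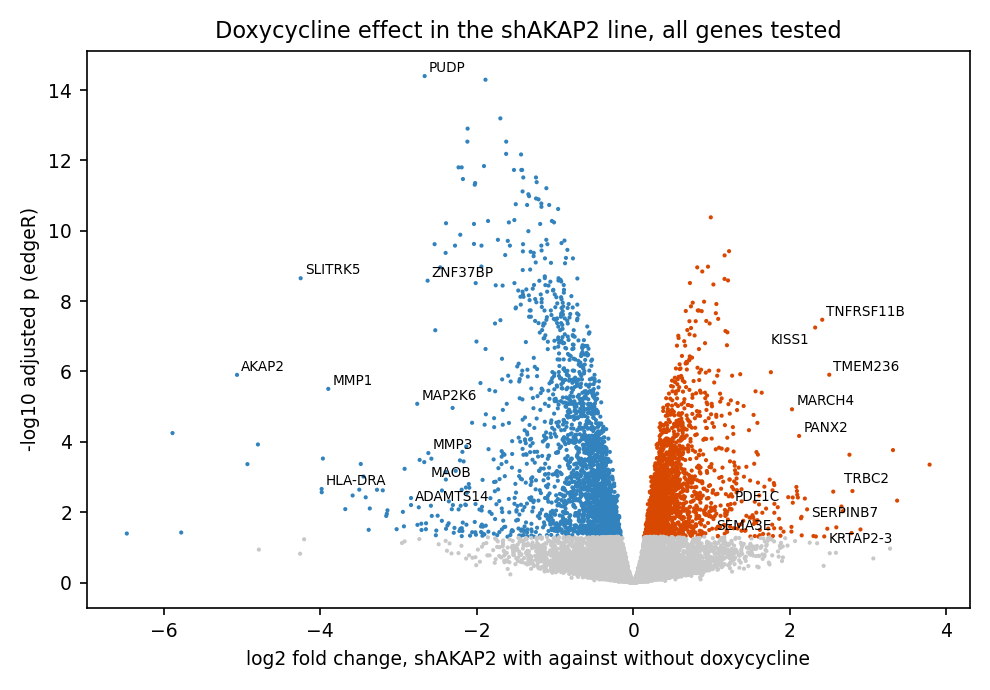
Each point is a gene; the horizontal axis is the log2 fold change with against without doxycycline in the shAKAP2 line and the vertical axis is -log10 of the adjusted p from edgeR. Orange points are the 2032 genes called higher, blue points the 2373 called lower, grey points were not called, and the labelled genes are those named by the rule.

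Focal adhesion genes were lower on balance: of 51 tested, 6 were higher and 16 lower (7 and 16 adjusted over the list alone). PTK2, which encodes focal adhesion kinase, fell (log2 -1.24, SE 0.0584), as did the actin linker VCL (log2 -1.34, SE 0.068), RSU1 (log2 -0.75, SE 0.0715) and the adaptor CRK (log2 -0.60, SE 0.0612). The list passed camera (adjusted p = 0.0166), but not with an estimated correlation (adjusted p = 0.722). PTK2, VCL and CRK hold 1 copy of GAACACA and RSU1 holds 2; without the genes that hold the word the adjusted p was 0.242.

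Metastasis genes of MDA-MB-231, chosen from general knowledge of genes tied to lung, bone or brain spread of this line, had 2 higher and 9 lower members of 28 (2 and 9 adjusted over the list alone). TNC, a matrix glycoprotein, fell (log2 -2.28, SE 0.144), with the growth factor gene EREG (log2 -1.31, SE 0.111), the chemokine receptor gene CXCR4 (log2 -1.89, SE 0.191) and LTBP1 (log2 -1.27, SE 0.134). The adjusted p was 0.00491 with camera, 0.0725 with an estimated correlation and 0.0875 without the genes that hold GAACACA. TNC and EREG hold 1 copy of the word, CXCR4 and LTBP1 none.

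Cholesterol synthesis genes rose: 15 were higher and 1 lower of 25 (19 and 1 adjusted over the list alone), among them SC5D (log2 0.93, SE 0.135), SQLE (log2 0.85, SE 0.164) and NSDHL (log2 0.57, SE 0.0986). The camera adjusted p was 2.97e-05 and that with an estimated correlation 0.722. Of 47 cytosolic ribosomal protein genes, 25 were higher and 0 lower (29 and 0 adjusted over the list alone), with small changes such as 0.34 for RPL22 (SE 0.0505) and 0.33 for RPL3 (SE 0.0615); the adjusted p was 3.13e-05, and 0.839 with an estimated correlation.

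Measures of RNA selection and quality moved with the induction as well. Of 12 replication-dependent histone genes, most of whose transcripts lack a poly(A) tail, 4 were higher and 0 lower (4 and 0 adjusted over the list alone), HIST1H1C 2.08-fold (SE of the log2 value 0.0904) and HIST1H2BK by log2 0.74 (SE 0.0611), with adjusted p = 0.00491, and 0.183 with an estimated correlation. Of 13 mitochondrially encoded transcripts, 0 were higher and 5 lower (0 and 6 adjusted over the list alone), including MT-ND6 (log2 -0.87, SE 0.174) and MT-ND5 (log2 -0.83, SE 0.169); the adjusted p was 0.0166, and 0.866 with an estimated correlation.

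The remaining lists did not pass camera in this comparison. Among adhesion and matrix lists, counts higher and lower (with those adjusted over the list alone) were 1 and 7 of 16 integrins (1 and 7; adjusted p = 0.148), 14 and 4 of 40 actin and myosin genes (17 and 6; 0.109), 9 and 11 of 43 extracellular matrix genes (9 and 11; 0.653), and 8 and 9 of 30 matrix proteases and inhibitors (8 and 10; 0.682). Mesenchymal genes had 1 and 6 of 19 (1 and 7; 0.148) and epithelial genes 4 and 2 of 21 (4 and 2; 0.303). YAP/TAZ targets had 9 and 4 of 23 (9 and 4; 0.376), SRF/MRTF targets 6 and 5 of 26 (6 and 6; 0.649), TGF-beta response 6 and 6 of 28 (7 and 6; 0.659) and MAPK output 3 and 8 of 21 (3 and 8; 0.148).

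Protein kinase A and A-kinase anchors had 3 higher and 9 lower of 26 (4 and 10; adjusted p = 0.129), among them the regulatory subunit genes PRKAR1A (log2 -0.65, SE 0.0655) and PRKAR2A (log2 -0.62, SE 0.0873), the catalytic subunit gene PRKACB (log2 -0.75, SE 0.0907) and AKAP9 (log2 -0.96, SE 0.13), all lower. PRKAR2A holds 1 copy of GAACACA, and PRKAR1A, PRKACB and AKAP9 hold none. cAMP/CREB targets had 5 and 7 of 28 (5 and 7; 0.376). Cell cycle lists had 4 and 3 of 38 for G1/S and DNA replication (3 and 3; 0.62) and 4 and 2 of 40 for G2/M and mitosis (4 and 2; 0.416). p53 targets had 4 and 1 of 24 (4 and 1; 0.148) and apoptosis 8 and 7 of 30 (10 and 8; 0.262). The interferon response had 1 and 10 of 43 (1 and 10; 0.0512). It passed as lower without the genes that hold GAACACA (camera adjusted p = 0.0232 with the preset correlation). With an estimated correlation the whole interferon list had a camera adjusted p = 0.722. The NF-kB response had 4 and 5 of 33 (4 and 5; 0.566).

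Nuclear-encoded oxidative phosphorylation had 10 higher and 2 lower of 48 (10 and 1; adjusted p = 0.0707), the integrated stress response 8 and 5 of 36 (9 and 5; 0.226), the unfolded protein response 8 and 4 of 25 (8 and 4; 0.566), glycolysis 2 and 6 of 24 (2 and 7; 0.625), hypoxia 1 and 9 of 29 (1 and 9; 0.129) and MYC targets and ribosome biogenesis 9 and 2 of 34 (9 and 2; 0.129). Markers of other cell types had 1 and 2 of 9 for luminal epithelium (1 and 2; 0.934), 1 and 1 of 10 for blood cells (1 and 1; 0.798) and 0 and 4 of 9 for fibroblasts (0 and 4; 0.13). Luminal markers had a median of 0.02 and a mean of -0.35 on the log2 scale, which differ in sign, and camera ranked them up; TGF-beta response genes had a median of -0.03 and a mean of 0.07 and ranked up.

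The shScramble line with against without doxycycline measured what the drug and a control hairpin did. Among the genes named by the rule, with a mean of at least 1 CPM and no overlap between groups, MMP9, which encodes gelatinase B and is among 13 myeloid genes described with the lists, rose 8.39-fold (log2 3.07, SE 0.513) and MMP3 rose 3.86-fold (log2 1.95, SE 0.433). PI16 rose by log2 1.41 (SE 0.193), ITGB2, the leukocyte integrin chain, by 1.28 (SE 0.181) and MYO1F by 1.49 (SE 0.309). HSD17B10, a mitochondrial dehydrogenase, fell from 52.6 ± 6.66 to 18.4 ± 0.706 CPM (log2 -1.51, SE 0.085, n = 4 each), with NCEH1 (log2 -1.32, SE 0.109), the histone variant gene H2AFX (log2 -1.18, SE 0.109), SLITRK5 (log2 -1.79, SE 0.268) and PRKAR2A-AS1 (log2 -1.14, SE 0.273). In all, 87 genes were higher and 81 lower of 15566, and 1456 had an unadjusted p under 0.05.

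These calls were unstable. Without both shScramble replicate 1 libraries, which lie far from their groups and were left out after this was seen, 588 genes were higher and 414 lower. Leaving out replicate 1 gave 241 higher genes in either condition, with 168 lower without the uninduced and 163 without the induced library. Without any other single library the higher genes numbered 41 (uninduced replicate 2), 48 (3), 47 (4), 47 (induced replicate 2), 48 (3) and 45 (4). MMP3 lost its call without any of the 6 libraries other than replicate 1, MYO1F without uninduced replicates 2 or 4 or induced replicate 3, PRKAR2A-AS1 without any library but induced replicate 1, and MMP9 under limma-voom. MMP9 overlaps SLC12A5-AS1, and PRKAR2A-AS1 and ITGB2 overlap genes on the opposite strand.

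Lists that moved in the shScramble line did so with markers of other cell types. Blood cell markers had 2 higher and 0 lower of 10 (3 and 0 adjusted over the list alone), CD53 (log2 4.32, SE 0.837) and PTPRC (log2 2.62, SE 0.589), with adjusted p = 1.65e-06, and 0.055 with an estimated correlation. No uninduced shScramble library had over 3 counts of CD53 or over 15 of PTPRC, so the sizes of these changes are uncertain. Fibroblast markers had 1 and 0 of 9 (3 and 0 adjusted over the list alone), PDGFRB (log2 0.77, SE 0.155), with adjusted p = 3.21e-05, and 0.0273 with an estimated correlation. The interferon response had 4 and 0 of 43 (13 and 0 adjusted over the list alone), including DDX60 (log2 0.80, SE 0.0763), IFIT3 (log2 0.41, SE 0.0731) and IFIT1 (log2 0.41, SE 0.0842); its adjusted p was 6.48e-14, and 0.0273 with an estimated correlation. Matrix proteases and inhibitors had 3 and 0 of 30 (3 and 0 adjusted over the list alone), MMP9, MMP3 and PLAT (log2 0.57, SE 0.111), with adjusted p = 2.06e-05, and 0.0273 with an estimated correlation. The summed level of 13 myeloid genes, chosen after their values were seen and including MMP9, CD53 and PTPRC, was 3.75 ± 1.51 CPM without and 29.2 ± 16.6 CPM with doxycycline. Myeloid is only a label for this set, which also holds CCL5 of the NF-kB list and MMP9 of the matrix protease list. CXCL10 and SPP1 gave 8.08 and 7.11 CPM of the level with doxycycline.

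Other lists were higher with the preset correlation and not with an estimated one. Extracellular matrix genes had 5 higher and 0 lower of 43 (13 and 0 adjusted over the list alone; adjusted p = 6.48e-14, and 0.055 with an estimated correlation), including COL8A1 (log2 0.43, SE 0.0704) and MATN2 (log2 0.61, SE 0.118). YAP/TAZ targets had 3 and 0 of 23 (6 and 0 adjusted over the list alone; 2.11e-06, and adjusted p = 0.145 with an estimated correlation), including CYR61 (log2 0.36, SE 0.0676), and SRF/MRTF targets 2 and 0 of 26 (4 and 0; 9.54e-05, and adjusted p = 0.0583), including FHL1 (log2 0.73, SE 0.0766). Integrins had 1 and 0 of 16 (5 and 0; 3.28e-05, and adjusted p = 0.145) and mesenchymal genes 0 and 0 of 19 (4 and 0; 0.000727, and adjusted p = 0.0583). Focal adhesion genes had 0 and 0 of 51 (0 and 0; 0.0132, and adjusted p = 0.5), epithelial genes 0 and 0 of 21 (1 and 0; 0.0348, and adjusted p = 0.681), luminal markers 0 and 0 of 9 (0 and 0; 0.0378, and adjusted p = 0.681) and TGF-beta response 0 and 1 of 28 (2 and 1; 0.0345, and adjusted p = 0.429), the lower member being PMEPA1 (log2 -0.67, SE 0.101). Cytosolic ribosomal proteins, MYC targets and ribosome biogenesis, and G1/S and DNA replication ranked lower with 0 members called, at adjusted p = 1.49e-06, 0.0378 and 0.0266, and 0.668, 0.772 and 0.772 with an estimated correlation. Single libraries decided several of these calls. Without uninduced replicate 3 the adjusted p was 0.783 for G1/S and for MYC targets, 0.423 for epithelial genes, 0.353 for luminal markers and 0.159 for TGF-beta response; without uninduced replicate 4 it was 0.504, 0.504, 0.271, 0.246 and 0.243. Without induced replicate 1 it was 0.611, 0.91, 0.91, 0.684 and 0.0755, and without uninduced replicate 2 it was 0.115, 0.061, 0.115 and 0.061 for the former 4. TGF-beta response also lost its call without induced replicate 4 (0.0659), and focal adhesion without induced replicate 3 (0.0603) or 4 (0.238).

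Genes called in both lines were few. Of the 87 higher in shScramble, 21 were also higher in shAKAP2, where independent lists would share 11.4 (Fisher's exact test, p = 0.00576), and of the 81 lower, 23 were also lower (12.3, p = 0.00269). Opposite calls were found too by Fisher's exact test, with 21 genes higher in shAKAP2 and lower in shScramble (10.6, p = 0.00149) and 29 the other way (13.3, p = 2.92e-05). Across the 15566 genes, which are not independent replicates, the log2 fold changes of the lines had Pearson's r = -0.03 and Spearman's rho = -0.02. SLITRK5 was lower in both lines and MMP3 was lower in shAKAP2 and higher in shScramble.

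The difference between the doxycycline effects tested which responses to doxycycline differed between the lines. Each hairpin was carried by its own line, so hairpin and line cannot be told apart. Changes within the shScramble line enter this difference too. The doxycycline effect in shAKAP2 minus that in shScramble was positive for PANX2 (log2 3.01, SE 0.496), KISS1 (log2 2.14, SE 0.282) and TNFRSF11B (log2 1.96, SE 0.287), and negative for MMP3 (log2 -4.57, SE 0.633), MMP1 (log2 -3.73, SE 0.482), HLA-DRA (log2 -3.97, SE 0.973) and PUDP (log2 -2.97, SE 0.104). The difference was 2.36 for PRKCQ-AS1, 2.25 for TMEM236, 2.23 for SLC16A14, 2.12 for the myosin gene MYO1D, 2.06 for PRKAR2A-AS1, 2.05 for PDE1C and 1.99 for HIST1H3H. It was -3.08 for the peptidase gene ANPEP, -3.05 for the chemokine gene CCL5, -2.99 for CAPN11, -2.95 for MAOB and -2.91 for MAP2K6. Higher and lower refer here to this difference of effects, not to levels: KISS1 stood at 6.26 ± 0.811 CPM in induced shAKAP2 and 8.42 ± 1.54 CPM in induced shScramble cells (SD, n = 4 each). In all 1172 genes were higher and 1630 lower, 150 and 508 of them at least 2-fold; 1022 of the higher and 1468 of the lower genes were also called in that direction in the shAKAP2 line. CCL5 is among the 13 myeloid genes. HLA-DRA lost its call under limma-voom, PDE1C and CCL5 without the low-count filter, and PRKAR2A-AS1 overlaps PRKAR2A. Without both shScramble replicate 1 libraries, left out after they were seen to lie apart, 2256 genes were higher and 2567 lower.

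Focal adhesion, integrin and matrix lists were lower in this test. Actin and myosin genes did not pass (5 higher and 4 lower of 40; 7 and 5 adjusted over the list alone; adjusted p = 0.235). Focal adhesion had 2 higher and 15 lower of 51 (5 and 18 adjusted over the list alone), with PTK2 at log2 -1.43 (SE 0.0815), VCL at -1.54 (SE 0.0949), RSU1 at -0.81 (SE 0.1) and CAV1 at -0.73 (SE 0.0964); the adjusted p was 0.000944, and 0.362 with an estimated correlation. Without the genes that hold GAACACA it was 0.0521. Integrins had 0 and 5 of 16 (0 and 9 adjusted over the list alone), among them ITGB2 (log2 -1.86, SE 0.257), ITGA5 (log2 -0.76, SE 0.123) and ITGB4 (log2 -0.96, SE 0.164), with adjusted p = 0.00306, and 0.362 with an estimated correlation. Extracellular matrix had 2 and 14 of 43 (2 and 17 adjusted over the list alone), with TNC (log2 -2.27, SE 0.197) and MATN2 (log2 -1.35, SE 0.169) lower and COL4A2 higher (log2 0.95, SE 0.136), at adjusted p = 0.00168, and 0.439 with an estimated correlation. Matrix proteases and inhibitors had 5 and 10 of 30 (5 and 12 adjusted over the list alone), with PLAT (log2 -1.58, SE 0.159) lower and PLAUR, the urokinase receptor gene, higher (log2 0.98, SE 0.125), at adjusted p = 0.0466, and 0.362 with an estimated correlation. Integrins, extracellular matrix and matrix proteases did not pass in the shAKAP2 line (adjusted p = 0.148, 0.653 and 0.682). They were higher in the shScramble line (3.28e-05, 6.48e-14 and 2.06e-05, and 0.145, 0.055 and 0.0273 with an estimated correlation). Their median log2 changes were -0.268, -0.0625 and -0.234 in the shAKAP2 line. In the shScramble line they were 0.214, 0.239 and 0.117. Both lines thus enter these 3 calls, and for extracellular matrix mostly the shScramble line.

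Metastasis genes of MDA-MB-231 had 1 higher and 8 lower of 28 (1 and 8 adjusted over the list alone), with CXCR4 (log2 -1.69, SE 0.244) and LTBP1 (log2 -1.20, SE 0.186) beside TNC and MMP1. This was the only list to pass both ways, at adjusted p = 0.000944, and 0.0336 with an estimated correlation, and it passed without the genes that hold GAACACA (adjusted p = 0.0054). Without those genes the list was higher in the shScramble line (adjusted p = 0.0324, against 0.236 with them) and did not pass in the shAKAP2 line (0.0875), so that call rests partly on the shScramble line. Mesenchymal genes had 0 and 6 of 19 (0 and 9 adjusted over the list alone), including ZEB1 (log2 -0.64, SE 0.0882) and DCN (log2 -7.87, SE 1.12), with adjusted p = 0.00788, and 0.192 with an estimated correlation. The difference for DCN was larger than for AKAP2 (log2 -5.65). Yet DCN did not meet the naming rule, which asks for a mean of at least 1 CPM and no overlap. The size of its difference is thus uncertain. The interferon response had 0 and 16 of 43 (1 and 17 adjusted over the list alone), including DDX60 (log2 -1.49, SE 0.109), DDX58 (log2 -0.94, SE 0.0987), IFIT3 (log2 -0.84, SE 0.104) and OAS2 (log2 -0.82, SE 0.11), with adjusted p = 1.7e-06, and 0.164 with an estimated correlation. Mesenchymal genes and the interferon response also did not pass in the shAKAP2 line (adjusted p = 0.148 and 0.0512) and were higher in the shScramble line (0.000727 and 6.48e-14). The shScramble values were 0.0583 and 0.0273 with an estimated correlation. Hypoxia genes had 1 and 5 of 29 (1 and 7 adjusted over the list alone), with STC1 (log2 -0.63, SE 0.108) and PLOD2 (log2 -1.93, SE 0.309) lower and ADM higher (log2 1.27, SE 0.112), at adjusted p = 0.0399, and 0.715 with an estimated correlation. DCN, OAS2 and PLOD2 hold 1 copy of GAACACA each, while ZEB1, DDX60, DDX58, IFIT3, STC1 and ADM hold none.

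Biosynthetic lists were higher. Cytosolic ribosomal proteins had 26 higher and 0 lower of 47 (35 and 0 adjusted over the list alone), including RPL23 (log2 0.39, SE 0.078), with adjusted p = 6.92e-09, and 0.441 with an estimated correlation. Cholesterol synthesis had 9 and 0 of 25 (11 and 0 adjusted over the list alone), including NSDHL (log2 0.70, SE 0.138) and MVK (log2 1.32, SE 0.316), with adjusted p = 4.55e-06, and 0.439 with an estimated correlation. MYC targets and ribosome biogenesis had 5 and 1 of 34 (5 and 1 adjusted over the list alone), including FBL (log2 0.49, SE 0.116), at adjusted p = 0.016, and 0.715 with an estimated correlation. Nuclear-encoded oxidative phosphorylation had 4 and 0 of 48 (1 and 0 adjusted over the list alone), including SDHD (log2 0.53, SE 0.104), at adjusted p = 0.0135, and 0.715 with an estimated correlation.

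The same test separated the markers of RNA selection and of other cell types. Histones had 5 higher and 0 lower of 12 (5 and 0 adjusted over the list alone), HIST1H1C by log2 1.09 (SE 0.128), with adjusted p = 0.00168, and 0.145 with an estimated correlation. Mitochondrially encoded transcripts had 0 and 2 of 13 (0 and 2 adjusted over the list alone), MT-ND6 (log2 -0.87, SE 0.244) and MT-ND5 (log2 -0.80, SE 0.237), with adjusted p = 0.0345, and 0.715 with an estimated correlation. Fibroblast markers had 0 and 5 of 9 (0 and 5 adjusted over the list alone), including DCN, COL1A2 (log2 -1.93, SE 0.357) and COL3A1 (log2 -3.80, SE 0.94), with adjusted p = 0.00168, and 0.145 with an estimated correlation. Blood cell markers had 1 and 4 of 10 (1 and 4 adjusted over the list alone), the lower ones CD53 (log2 -4.48, SE 1.05), PTPRC (log2 -3.31, SE 0.789), SPI1 (log2 -4.26, SE 1.19) and CSF1R (log2 -1.02, SE 0.224), with adjusted p = 0.0399, and 0.439 with an estimated correlation. CD53, PTPRC and SPI1 did not meet the naming rule. Uninduced shScramble libraries had at most 3 counts of CD53 and 15 of PTPRC. Fibroblast and blood cell markers did not pass in the shAKAP2 line (adjusted p = 0.13 and 0.798) and were higher in the shScramble line (3.21e-05 and 1.65e-06). The shScramble values were 0.0273 and 0.055 with an estimated correlation. Leaving out any of 12 libraries ended the call for blood cell markers (adjusted p 0.0508 to 0.117), any of 7 that for mitochondrially encoded transcripts (0.0522 to 0.15), any of 8 that for matrix proteases (0.05 to 0.0914) and any of 5 that for hypoxia (0.0517 to 0.164). MYC targets lost the call without shScramble uninduced replicate 3 (0.078) or 4 (0.0604) or induced replicate 1 (0.164), and oxidative phosphorylation without uninduced replicate 3 (0.0508) or induced replicate 4 (0.0522). Without the genes that hold GAACACA the adjusted p was 0.0509 for matrix proteases, 0.0565 for oxidative phosphorylation and 0.0565 for hypoxia. Without both shScramble replicate 1 libraries it was 0.0881 for mitochondrially encoded transcripts and 0.0572 for blood cell markers.

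**Figure D3:**
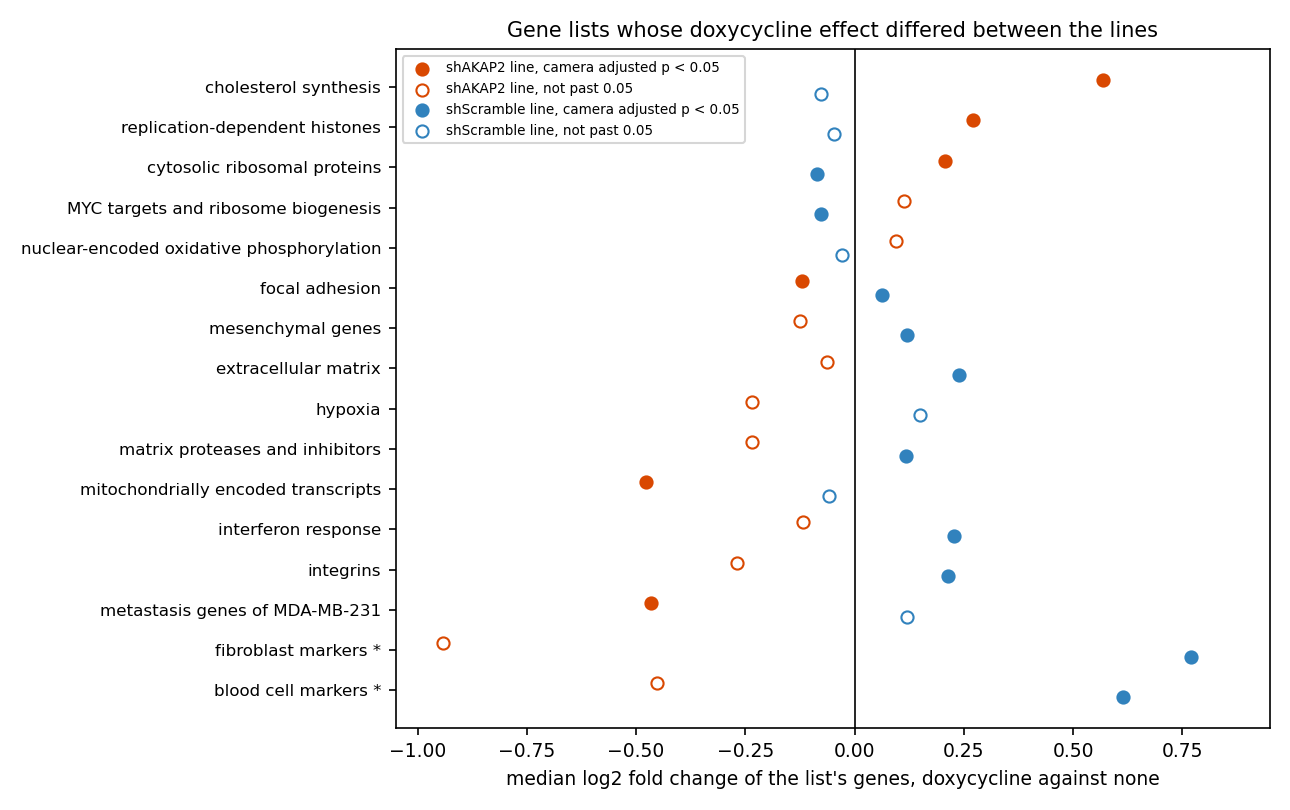
Median log2 fold change with against without doxycycline (horizontal axis) of the 16 gene lists whose doxycycline effect differed between the lines; orange points are the shAKAP2 line and blue points the shScramble line, filled where the list passed camera in that line, and stars mark markers of another cell type. Cholesterol synthesis lies at 0.57 in shAKAP2 and -0.08 in shScramble, and metastasis genes of MDA-MB-231 at -0.47 and 0.12.

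The lines were also compared with each other under doxycycline, where the induced AKAP2 hairpin met the induced control. The shAKAP2 line was lower in HLA-DRA (log2 -6.43, SE 0.785), HLA-DPB1 (log2 -5.61, SE 1.01), HLA-DRB1 (log2 -5.43, SE 0.805), MMP1 (log2 -5.66, SE 0.385) and the steroid dehydrogenase gene HSD3B1 (log2 -5.69, SE 1.09). It was higher in GLB1L2, 12-fold (log2 3.58, SE 0.249), SEL1L3 (log2 3.38, SE 0.33), PANX2 (log2 3.36, SE 0.362), PRKCQ-AS1 (log2 2.44, SE 0.392) and SLC16A14 (log2 2.42, SE 0.336). In all 2911 genes were higher and 3340 lower, 296 and 1148 of them at least 2-fold. HLA genes have close paralogs, and shScramble replicate 1 stands apart for HLA-DRA, HLA-DPB1, HLA-DRB1 and HSD3B1.

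Metastasis genes of MDA-MB-231 had 3 higher and 16 lower of 28 (3 and 16 adjusted over the list alone), with CXCR4 (log2 -3.59, SE 0.186) and SRGN (log2 -2.22, SE 0.13) lowest in p, at adjusted p = 4.37e-05, and 0.00805 with an estimated correlation. Without doxycycline the list did not pass between the lines, with 7 and 9 of 28 (8 and 13 adjusted over the list alone) and adjusted p = 0.0823, and 0.735 with an estimated correlation. In settings chosen after seeing the data, that adjusted p was 0.0294 without both shScramble replicate 1 libraries and 0.0286 without the genes that hold GAACACA. Histones had 7 and 0 of 12 (7 and 0 adjusted over the list alone), at adjusted p = 4.37e-05, and 0.0313 with an estimated correlation, while 12 further lists passed with the preset correlation alone. Among those, the interferon response had 3 and 27 of 43 (3 and 27 adjusted over the list alone; adjusted p = 1.91e-06, and 0.218 with an estimated correlation), led by DDX60 (log2 -1.27, SE 0.0777) and IRF1 (log2 -1.56, SE 0.105). IRF1 holds 1 copy of GAACACA and DDX60 none. Mitochondrially encoded transcripts had 0 and 11 of 13 (0 and 11 adjusted over the list alone; 0.000141, and adjusted p = 0.754 with an estimated correlation) and fibroblast markers 1 and 5 of 9 (2 and 5; 0.0236, and adjusted p = 0.506). Focal adhesion had 11 and 21 of 51 (13 and 22; 0.023, and adjusted p = 0.754), which was 0.306 without the genes that hold GAACACA, and MYC targets 23 and 1 of 34 (24 and 1; 2.03e-05, and adjusted p = 0.754). Focal adhesion lost its call without shScramble replicate 4 with doxycycline (0.0779). Integrins, mesenchymal genes and luminal markers did not pass (adjusted p = 0.0786, 0.139 and 0.0568), but were lower without the genes that hold GAACACA (0.0211, 0.0466 and 0.0294). These are camera values with the preset correlation, and with an estimated one the whole lists had adjusted p = 0.81, 0.754 and 0.81.

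Without doxycycline, where neither hairpin was induced, the lines already differed. PDE1C was lower in shAKAP2, at 0.287 ± 0.193 against 14 ± 2.8 CPM (log2 -5.59, SE 0.4, n = 4 each), with TRBC2 (log2 -3.50, SE 0.573), the cystatin gene CST1 (log2 -3.43, SE 0.734), HSD3B1 (log2 -3.27, SE 1.01) and RNASE1 (log2 -3.20, SE 0.78). GLB1L2 was higher (log2 3.14, SE 0.242), as were the chemokine genes CXCL9 (log2 4.22, SE 0.903) and CXCL10 (log2 3.17, SE 0.56), SPP1, which encodes osteopontin (log2 3.25, SE 0.639), and PLEK (log2 3.22, SE 0.657). CXCL9, CXCL10, SPP1 and PLEK are among the 13 myeloid genes, whose sum was 35.5 ± 7.22 CPM here. In all 1346 genes were higher and 1449 lower, 126 and 361 of them at least 2-fold. HSD3B1 lost its call when any of 5 single libraries was left out, and without both shScramble replicate 1 libraries 2130 genes were higher. Leaving out single libraries gave 750 to 1208 higher and 919 to 1385 lower genes, with 750 and 919 without uninduced shAKAP2 replicate 1 and 802 and 947 without replicate 2.

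The lists that passed here were lost with an estimated correlation (adjusted p = 0.844 for each). Nuclear-encoded oxidative phosphorylation had 1 higher and 12 lower of 48 (2 and 18 adjusted over the list alone; adjusted p = 0.00356), led by NDUFA1 (log2 -0.86, SE 0.0761), and mitochondrially encoded transcripts 0 and 1 of 13 (0 and 4; 0.00836). MYC targets had 7 and 0 of 34 (8 and 0; 0.00356), cytosolic ribosomal proteins 3 and 6 of 47 (3 and 14; 0.00836), cholesterol synthesis 0 and 1 of 25 (0 and 1; 0.038), luminal markers 0 and 3 of 9 (0 and 5; 0.0395), and blood cell markers 4 and 1 of 10 (5 and 1; 0.038), the higher ones including CD53 (log2 4.35, SE 0.837) and PTPRC (log2 2.61, SE 0.59). CD53 and PTPRC had at most 3 and 15 counts in an uninduced shScramble library. Leaving out shScramble replicate 1 without doxycycline ended the calls for cholesterol synthesis (adjusted p = 0.351), luminal markers (0.182), MYC targets (0.145), mitochondrially encoded transcripts (0.0856) and blood cell markers (0.052). Without uninduced shAKAP2 replicate 3 it was 0.0784 for cholesterol synthesis, luminal and blood cell markers, and without replicate 4 it was 0.0507 for luminal markers and cytosolic ribosomal proteins. Cholesterol synthesis also lost its call without shScramble replicate 2 (0.0531) or shAKAP2 replicate 1 (0.0519). Without the genes that hold GAACACA the adjusted p was 0.0508 for cholesterol synthesis and 0.0545 for luminal markers.

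Of the genes that differed between lines with doxycycline, 655 higher and 887 lower also differed in that direction without it, where independent lists would share 252 and 311. Across genes, which are not independent replicates, the log2 differences with and without doxycycline had Pearson's r = 0.49 and Spearman's rho = 0.42. These comparisons share no libraries.

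**Figure D4:**
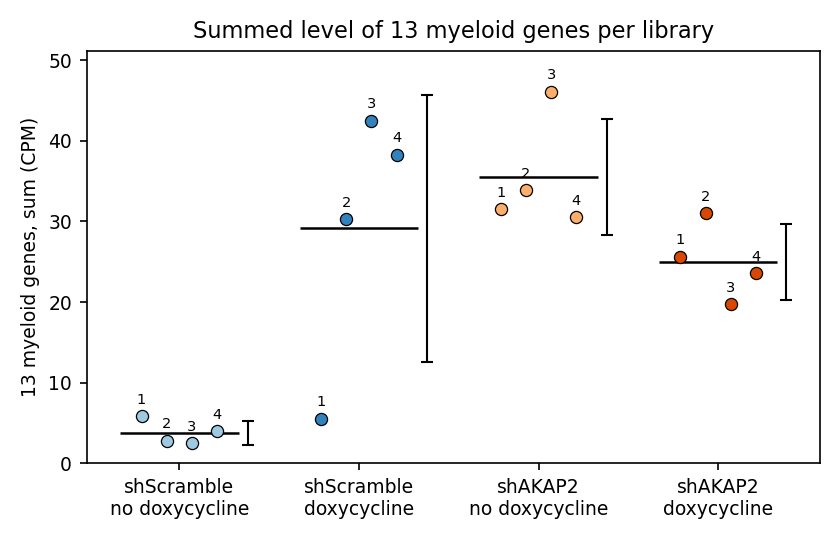
Summed level of 13 myeloid genes in CPM (vertical axis) per library by group (horizontal axis); points are libraries numbered by replicate, the line is the mean and the bar is 1 SD either side of it. The 4 shScramble libraries without doxycycline and shScramble replicate 1 with it lie at 5.8 CPM or lower, and the other 11 libraries at 19.7 CPM or higher.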

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

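Of the tests below, those on the shared 3' UTR word itself and those of doxycycline and cell line for the myeloid genes were chosen only after the result was seen. The rule by which the myeloid composition test is read was tightened after its value was seen.

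The doxycycline effect differed between the lines, by the interaction term of edgeR's quasi-likelihood test, with a higher effect in shAKAP2 than in shScramble for 1172 genes and a lower effect for 1630. The log2 difference was -5.65 for AKAP2, -4.57 for MMP3, -3.97 for HLA-DRA, -3.73 for MMP1, -3.08 for ANPEP, -3.05 for CCL5, -2.99 for CAPN11, -2.97 for PUDP, -2.95 for MAOB and -2.91 for MAP2K6. It was 3.01 for PANX2, 2.36 for PRKCQ-AS1, 2.25 for TMEM236, 2.23 for SLC16A14, 2.14 for KISS1, 2.12 for MYO1D, 2.06 for PRKAR2A-AS1, 2.05 for PDE1C, 1.99 for HIST1H3H and 1.96 for TNFRSF11B.

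By the same term and camera with the preset correlation, lists were lower at an adjusted p of 1.7e-06 for the interferon response, 0.000944 for focal adhesion and for metastasis genes of MDA-MB-231, 0.00168 for extracellular matrix and for fibroblast markers, 0.00306 for integrins, 0.00788 for mesenchymal genes, 0.0345 for mitochondrially encoded transcripts, 0.0399 for hypoxia and for blood cell markers, and 0.0466 for matrix proteases and inhibitors. Lists were higher at 6.92e-09 for cytosolic ribosomal proteins, 4.55e-06 for cholesterol synthesis, 0.00168 for histones, 0.0135 for oxidative phosphorylation and 0.016 for MYC targets. With an estimated correlation only the metastasis genes passed (adjusted p = 0.0336), and the adjusted p of the other lists was 0.145 to 0.715. Integrins, extracellular matrix, matrix proteases, mesenchymal genes, the interferon response, fibroblast and blood cell markers did not pass in the shAKAP2 line and were higher in the shScramble line. Of these, only matrix proteases, the interferon response and fibroblast markers passed in the shScramble line with an estimated correlation (camera adjusted p = 0.0273 each).

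Other splits of the same libraries were counted for each comparison. In the shAKAP2 line 1 of 35 splits, the real one, called as many genes (4405, against 0 at most in the others). That is the smallest share 35 splits can give, and the other splits mix groups that differ. Chance is thus made unlikely for that count but is not excluded. The same held between lines with doxycycline (1 of 35; 6251 against at most 42) and without it (1 of 35; 2795 against at most 0). In the shScramble line 3 of 35 splits called as many as the real 168, so chance is not excluded; the split of replicates 1 and 2 against 3 and 4 of both conditions called 1054, which points to a structure of the samples. For the interaction 5 of 100 splits drawn called as many as the real 2802, with 3300 at most, so chance is not excluded by that count. All 4 of the others kept the shAKAP2 libraries grouped as labelled, and the highest count with them mixed was 7.

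The first pattern is the 7-letter word GAACACA, found by a scan of 16357 words in the 3' UTRs of 12807 genes, so it is a hypothesis found and tested on the same data. Its score was -20.49 in the shAKAP2 line, against 4.72 at most when fold changes were shuffled among genes 100 times, 1.04 in the shScramble line and -0.06 between uninduced lines, and -10.18 in coding sequence. Base composition was tested with other orders of the same letters: the most extreme was -14.69, for an order that overlaps the word by a shift, which left the test undecided, and a second test, added for that reason, gave -4.09 among orders that share no run of 5 letters. Among genes with the word the log2 fold change, adjusted for 3' UTR length, fell by 0.155 per further site (permutation p = 5e-05), which is consistent with the induced hairpin acting on other transcripts through a seed match, but without that adjustment the deepening was smaller, with medians of -0.25, -0.29 and -0.37 for 1, 2 and 3 or more sites and 39.9%, 47.3% and 46.3% of genes called lower. AKAP2 holds 1 site (GRCh38 chromosome 9, 110169258 to 110169264, plus strand, base 761 of 4015 of its 3' UTR). The hairpin sequence is not given in the sources used here, and no other AKAP2 hairpin was analysed here. Loss of AKAP2 and effects of its hairpin on other transcripts thus stay open for the other genes that changed in the shAKAP2 line. That holds for genes with the word, and the scan of words does not settle it for genes without it.

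For the gene lists, the same explanation was set against the members without the word in the interaction. The 8 focal adhesion members with the word had a mean log2 difference of -0.89, against -0.15 for the others (permutation p = 0.00039). Without genes that hold it, focal adhesion had a camera p of 0.0232, past the bound written beforehand against the word as the whole cause. The test cannot decide this, because the whole list was higher in the shScramble line (camera adjusted p = 0.0132), which enters the interaction. The adjusted p was 0.0521, and in the shAKAP2 line alone the camera p was 0.154. Genes with the word in coding sequence alone, where it scored -10.18 in the shAKAP2 line, also stayed in. The word may account for much of that list's shift. Metastasis genes of MDA-MB-231 had a camera p of 0.00131 without it and an adjusted p of 0.0054. That call rests partly on the shScramble line, where the list without those genes was higher (adjusted p = 0.0324), while in the shAKAP2 line it did not pass (adjusted p = 0.0875).

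The second pattern is the 13 myeloid genes, chosen after their values were seen, whose sum was 2.49 to 5.8 CPM in uninduced shScramble libraries. The pattern followed neither doxycycline nor the cell line alone. Of the libraries without doxycycline, 5 lay above the lowest library with it, and 3 shScramble libraries lay inside the range of the shAKAP2 libraries. Because the genes were chosen with these values in view, both counts restate the pattern, and no conclusion on a cause is drawn from them. RNA or reads from another sample would keep the genes in 1 ratio. Over the 11 libraries that hold them the chi-square per degree of freedom was 3.44. The median was 6.39 for random gene sets, and 0.1% of 1000 such sets were as low. Counting error alone around 1 ratio would give a value near 1, so the counts spread more than 1 exact ratio gives. The choice of genes with their values in view also favoured a value below that of random sets. Random sets carry real group effects, and genes regulated together would be low too. RNA or reads from another sample thus cannot be told apart from expression in these cells by this test. LYZ reached 0.792 CPM at most and C1QA 0.0783 CPM. Expression that differs between cultures was not tested.

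The third pattern is shScramble replicate 1, which lay 0.504 (uninduced) and 0.539 (induced) from its group, against 0.396 at most for the other 14 libraries. The distance was at least 0.509 after thinning and at least 0.506 without the 100 most abundant genes. The highest of the other 14 libraries was then 0.393 and 0.396. The distance thus hardly responded to either change in any library, so these tests cannot decide on depth or on a few abundant genes. Induced replicate 1 had 26235862 counts, between induced replicates 3 (25411278) and 2 (29381340), so its depth did not stand apart. The deviations of the replicate 1 libraries had a correlation of 0.4. A separate culture or batch sharing that number stays open, and no biological explanation was tested, since the design gives none.

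Of 114 groups of 4 libraries tested for a library far from the rest, 14 had one, where chance gives about 1 in 20, or 5.7. In 10 of them it was shScramble replicate 1, with the gap as a share of the range at 0.88 for MMP3, 0.891 for HLA-DRA, 0.905 for HSD3B1, 0.942 for HLA-DPB1 and 0.831 for HLA-DRB1 with doxycycline, and at 0.913 for HSD3B1, 0.908 for CXCL9, 0.944 for CXCL10, 0.916 for CST1 and 0.937 for RNASE1 without it. The others were KISS1 in uninduced shAKAP2 (0.947, replicate 3), MAOB in uninduced (0.87, replicate 1) and induced shAKAP2 (0.919, replicate 3), and PDE1C in uninduced shScramble (0.923, replicate 4).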

How the results depend on the processing

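The alternatives without both shScramble replicate 1 libraries, without genes that hold GAACACA and with a block within each line were chosen after seeing the data; the others were planned. Of 1644 alternatives over 68 results of named genes, 1579 kept the direction and the side of the threshold, 65 kept the direction without passing and 0 reversed. Under the scaling alternatives the median log2 value of all genes was at most 0.041 in size, for the interaction with upper-quartile factors, against 0.0032 with TMM. Low counts limit AKAP2 in the induced shAKAP2 line, with 4 counts in all. Except where stated, the cause of a change was not tested.

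Requiring an absolute log2 fold change of at least 1 left 202 genes higher and 485 lower in the shAKAP2 line, 21 and 11 in the shScramble line, 150 and 508 for the interaction, 296 and 1148 between lines with doxycycline and 126 and 361 without it. An adjusted p under 0.01 left 1235 higher in the shAKAP2 line, 34 and 51 in the shScramble line, 500 and 956 for the interaction, 1935 higher between lines with doxycycline, 514 and 637 without it, and 10 genes higher and 13 lower in both lines. These fall by construction.

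DESeq2 called 165 higher and 127 lower in the shScramble line. With only the 8 libraries compared, 3144 genes were higher in the shAKAP2 line, and 14 higher and 23 lower in the shScramble line. Without both shScramble replicate 1 libraries, 588 and 414 were called in the shScramble line, 2256 and 2567 for the interaction and 2130 higher between uninduced lines, with 6 lists lower in the shScramble line and 4 higher and 3 lower between uninduced lines. Leaving out the genes that hold GAACACA moved no count of genes by over 1.5 times.

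With an estimated correlation, camera called 0 lists higher and 0 lower in the shAKAP2 line, 3 and 0 in the shScramble line, 0 and 1 for the interaction, 1 and 1 between lines with doxycycline and 0 and 0 without it, against 3 and 3, 13 and 3, 5 and 11, 6 and 8, and 2 and 5 with the preset one. Under fry, which does not compare a list with other genes, 6 lists were higher and 10 lower in the shAKAP2 line, 0 lower in the shScramble line, 14 lower between lines with doxycycline and 3 without it. With a filter of at least 1 CPM in 4 libraries, 7 lists were lower for the interaction, and 1 higher and 3 lower between uninduced lines.

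Leaving out single libraries gave 1598 to 1812 higher and 1997 to 2216 lower genes in the shAKAP2 line, 41 to 241 and 54 to 168 in the shScramble line, 857 to 1607 and 1389 to 2029 for the interaction, 2540 to 2800 and 3007 to 3253 between lines with doxycycline and 750 to 1208 and 919 to 1385 without it. Lists numbered 3 to 4 higher and 3 to 5 lower in the shAKAP2 line, 10 to 18 and 1 to 5 in the shScramble line, 3 to 7 and 7 to 11 for the interaction, 4 to 6 and 6 to 9 between lines with doxycycline and 1 to 5 and 2 to 8 without it. The AKAP2 log2 fold change ranged from -6.42 to -4.67 in the shAKAP2 line.

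The labels give the groups the same replicate numbers without saying what a number shares. Of the same-numbered libraries, 2 of 24 correlations were over 0.1 (range -0.0996 to 0.4), and 6 of 16 libraries correlated best with their own number. Between the shScramble conditions they were 0.4, 0.0234, 0.197 and 0.0703 for replicates 1 to 4, so pairing was not taken as given, while a structure by number within that line is not excluded. With the number as a replicate block shared by both lines, 2097 genes were higher and 2446 lower in the shAKAP2 line, 93 and 80 in the shScramble line, 1192 and 1722 for the interaction, 2977 and 3352 between lines with doxycycline and 1404 and 1465 without it, and among named genes the call for PRKAR2A-AS1 in the shScramble line was lost. With a replicate block within each line, 2735 genes were higher and 2924 lower in the shAKAP2 line, 254 and 162 in the shScramble line, and 1820 and 2253 for the interaction, with 71 genes higher and 49 lower in both lines, and 6 lists lower in the shAKAP2 and 5 in the shScramble line. These hold 83 of the 87 higher and 81 of the 81 lower calls of the shScramble line, and the interaction call for CCL5 was lost.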

Other observations

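The genes described here, and the tests reported with them, were chosen after their values were seen. Some MHC class II genes, whose products present peptides to T cells, were called lower with doxycycline in the shAKAP2 line; they are single genes, not a list tested as a group. CIITA, the transactivator of this gene family, fell from 6.68 ± 0.306 to 1.6 ± 0.446 CPM (SD, n = 4 each; log2 -2.06, SE 0.293, adjusted p = 2.88e-05), and stood at 9.78 ± 4.75 and 10.2 ± 2.81 CPM in shScramble cells (adjusted p = 0.985). The difference between the lines' doxycycline effects was -2.11 for CIITA (SE 0.388, adjusted p = 0.000773), -3.97 for HLA-DRA (adjusted p = 0.0136) and -2.33 for HLA-DMB (adjusted p = 0.0338). CD74, the invariant chain, fell (log2 -1.39, SE 0.42, adjusted p = 0.0255), with HLA-DRB1 (log2 -2.52, adjusted p = 0.0454), but their differences between the lines' effects did not pass (adjusted p = 0.142 and 0.115). HLA-DPA1, HLA-DPB1 and HLA-DMA were not called (adjusted p = 0.196, 0.0679 and 0.118).

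RFX5, which binds MHC class II promoters, fell from 85 ± 4.34 to 59.6 ± 2.84 CPM (log2 -0.51, SE 0.0638, adjusted p = 3.81e-06), with a difference between the lines' effects of -0.46 (adjusted p = 0.0011), while its partners RFXAP and RFXANK were not called (adjusted p = 0.936 and 0.162). The uninduced lines already differed, in HLA-DRA by log2 -2.46 (adjusted p = 0.0122) and in CD74 by -1.43 (adjusted p = 0.0312). HLA-DRA holds 1 copy of GAACACA, HLA genes have close paralogs, and shScramble replicate 1 had the highest CD74 level of its line in both conditions (529.6 and 448.7 CPM, against 156.9 to 234 in the other libraries).

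In that replicate, several other genes stood outside the range of the 6 other shScramble libraries. Uninduced and induced levels were 110.7 and 89.84 CPM for CXCL8 (11.53 to 25.45 in the others), 2230 and 1885 CPM for SCD (199.5 to 812.5), 287.4 and 301.2 CPM for TNFSF10 (56.3 to 90.03), and 104.2 and 117.9 CPM for ODC1 (191.1 to 253.7).

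Among 3' UTR words, the word that led in the shScramble line was GTCGCCC, held by 596 genes, with a score of -8.77 against 4.88 at most over 100 shuffles. Its score was 0.24 in the shAKAP2 line, 4.51 for the difference of the doxycycline effects (4.45 at most over the shuffles), 4.66 between lines with doxycycline (4.65 at most) and 1.44 between lines without it.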
